A study of Mus musculus with 4 samples.

How the data were processed

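RNA was measured in 4 libraries of mouse splenic CD4+ T cells after 5 days of culture under Th1 conditions, 2 with PBS and 2 with IL-16. Per the labels' protocols, total RNA was purified on Qiagen RNeasy columns and polyadenylated RNA was made into libraries with a SMARTer mRNA kit. Groups and replicate numbers were taken from the sample titles, and each value column was matched to a sample by its name. The source and cell type labels of the same samples name peritoneal macrophages. The titles and the series' design text name Th1 cells. Marker levels are given per library without regrouping any sample by them.

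The deposited table has 26334 rows and 1 value per library. Its values were read as FPKM, which the authors computed before deposition. The table names no unit, and FPKM was inferred from values that are not whole numbers and from unequal column totals of 373924 to 391153. The tools fastp, HISAT2 and featureCounts and the build GRCm39 are named in the submitters' processing notes, without versions. The tool that produced the deposited values and the annotation it used are not given in the sources used here. The values were checked for steps that whole reads would leave. Among 1443 to 1587 genes under 0.2 FPKM in a pair of libraries, at most 1.18% of the ratios between libraries fell within any window of 0.5%. Reads were therefore not recovered and the sequencing depth is unknown. No interval or detection floor that needs read counts is therefore given. The table has 2832 rows named as newly assembled genes, 1607 rows that carry a copy suffix of a gene also in the table (614 of them tested) and 6869 rows at 0 in every library. In all, 21884 rows matched a symbol of the RefSeq annotation of GRCm38.p6. No coordinates are given because the reference annotation used here is of another build than the one in the notes. RefSeq served for names, and GENCODE vM21, also of GRCm38, for transcript length, GC content and the order and strand of genes.

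The tests fixed before the data were examined were count-based, and FPKM are not counts. They were replaced by the planned fallback for normalized values: limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(FPKM + 1), with group as the sole term. A row was tested if it reached 1 FPKM in at least 2 libraries, a filter chosen after the table had been seen, which left 11882 rows (788 newly assembled). Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all tested rows, with a threshold of 0.05. Fold changes in log2 are on the log2(FPKM + 1) scale, which understates the change of low genes, and linear folds are ratios of mean FPKM. Within groups the libraries correlated with Pearson's r of 0.989 (PBS) and 0.986 (IL-16) across tested rows, which are not independent replicates, and with r of 0.974 to 0.984 between groups. The median absolute log2 difference was 0.0864 within PBS and 0.142 within IL-16. Between groups it was 0.145 and 0.150 for IL-16 replicate 1 and 0.214 and 0.220 for IL-16 replicate 2, so the IL-16 libraries differed from each other about as much as IL-16 replicate 1 differed from PBS. No tested row had identical values in a pair of libraries, so all 4 were kept as separate samples.

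Before the data were examined, 40 gene lists with 805 members were fixed, of which 778 were in the table. They covered the Th1, Th2, Th17, Treg and Tfh programs, naive and memory genes, cytotoxic granules, inhibitory receptors, activation, cytokines, chemokine receptors and homing, type I interferon and IFN-γ responses, IL-2 and STAT5, NF-kB, glutamine, ATF4, glycolysis, hypoxia, the TCA cycle, respiratory chain subunits, cholesterol synthesis, S phase, mitosis, ribosome biogenesis, ribosomal proteins, the unfolded protein response, heat shock, p53 and apoptosis, histones, mitochondrially encoded genes and markers of 9 cell types. The 32 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The 8 other lists were 7 marker lists, given as levels, and the mitochondrially encoded genes, of which 0 were in the table. Members of each list were also adjusted over the list alone. Of the 11882 tested rows 2785 had an unadjusted p under 0.05. Counts over a list alone are therefore descriptive and not particular to a list.

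Genes to be named were fixed by rule before the data were examined. The rule took Il16, Cd4, Cd9, Ifng and Tbx21; up to 10 genes per direction with the largest fold change among those past the threshold with a mean of at least 5 (planned in CPM, applied to FPKM), no overlap between groups and a symbol that is not a clone, Gm number or pseudogene; and per list the 4 tested members with the smallest p. If fewer than 5 genes had passed in a direction, the 5 with the smallest p would have been named. Genes named outside this rule are said to be so. Some genes that the rule selects are not reported here.

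The procedure was tested on simulated data with the levels and spread of these libraries, 11882 genes and 200 changed genes in 10 simulations. It recovered 9.4% of genes changed by 0.5 on the log2 scale, 67.8% at 1, 89.8% at 1.5 and 96.0% at 2, with 7.8 false calls on average. A list of 25 genes shifted by 0.4 was called in 10 of 10 simulations with the preset correlation and in 0 of 10 with the estimated one, and 0 of 300 unshifted lists were called by either. The simulated genes varied independently of each other. These counts therefore do not show how often the preset correlation miscalls lists whose members move together.

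The alternatives were pseudocounts of 0.1 and 5, no filter on low values, each library left out in turn, the replicate number as a block, a 2-fold minimum, camera with an estimated correlation and fry. Added after the data were seen were median-of-ratios scaling, rescaling to TPM, a stricter filter of 5 FPKM in both libraries of a group, summing of copy rows with their gene, a spline correction per library for GC content and transcript length, and removal of ribosomal protein rows. Length and GC content were medians over protein-coding transcripts in GENCODE vM21 and covered 86.3% of tested rows. Figures were drawn with matplotlib 3.10.9.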

Results

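Gene expression was measured by bulk RNA sequencing of polyadenylated RNA in mouse CD4+ T cells that had been purified from spleen as naive cells and grown for 5 days under conditions that drive T helper 1 (Th1) differentiation. The cultures received either phosphate-buffered saline (PBS, the vehicle; n = 2 libraries) or interleukin-16 (IL-16; n = 2 libraries), a cytokine for which CD4 and CD9 have been described as receptors. Th1 cells are the interferon-gamma (IFN-γ) producing branch of CD4+ T cells, and the comparison asks how IL-16 alters gene expression in cells set on that path. The deposited table held 1 value per gene and library, read as FPKM, with library totals of 385907 and 391153 for the PBS libraries and 388218 and 373924 for the IL-16 libraries. The number of sequenced reads behind each value is unknown, so no counting error is given. A total of 11882 rows reached 1 FPKM in at least 2 libraries and were tested. Nothing in the sample descriptions says that the 2 libraries of a group came from separate animals or cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Camera at the preset correlation compares the genes of a list with the other tested genes, so its p-values do not measure that spread.

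The titles call the samples Th1 cells, whereas the source and cell type labels call them peritoneal macrophages. All 4 libraries carried the transcripts of CD4+ T cells. The median of 17 T cell markers was 126 and 138 FPKM in the PBS libraries and 141 and 142 FPKM in the IL-16 libraries, and Cd4 itself was 252 ± 13.2 FPKM (SD, n = 2) with PBS and 285 ± 22.8 FPKM (SD, n = 2) with IL-16. The median of 17 macrophage markers was between 0.0212 and 0.0501 FPKM. Of these, named after their values were seen, the macrophage colony-stimulating factor receptor gene Csf1r did not exceed 0.135 FPKM, F4/80 (Adgre1) did not exceed 0.117 FPKM, and the highest macrophage marker, Cd68, reached 4.88 FPKM. Median marker levels were between 4.12 and 4.99 FPKM for CD8 T cells (Cd8a and Cd8b1), between 0.766 and 1.19 FPKM for NK cells, between 0.601 and 1.11 FPKM for gamma-delta or NKT cells and between 0.159 and 0.206 FPKM for B cells. They were between 0.177 and 0.368 FPKM for dendritic cells, between 0.0811 and 0.292 FPKM for erythroid cells or platelets and between 0 and 0.0717 FPKM for neutrophils or mast cells. Single markers of these types stood higher, among them Klrd1 with up to 17.7 FPKM, Fcer1g with up to 11.8 FPKM, Ccl22 with up to 9.21 FPKM, Cxcr2 with 4.94 to 9.48 FPKM and Ly6g with 23.9 to 29.7 FPKM. The deposited table held 17 of 20 fixed T cell markers, 11 of 14 for B cells and 3 of 7 for gamma-delta or NKT cells. The immunoglobulin and T cell receptor constant region genes of these lists were not in it, so the medians do not cover them.

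**Figure D1:**
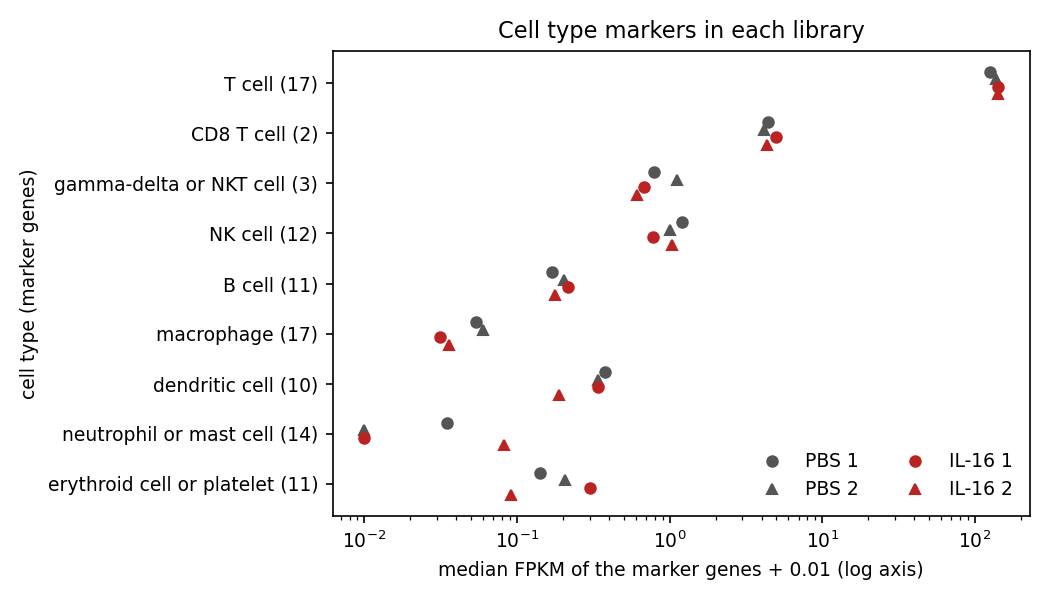
Median FPKM of the marker genes of 9 cell types in each library, with 0.01 added so that a median of 0 can be drawn on the log axis; circles are replicate 1, triangles replicate 2, grey PBS and red IL-16, and the number of marker genes is in brackets. T cell markers lie between 126 and 142 FPKM in the 4 libraries, and macrophage markers at or below 0.0501 FPKM.

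Th1 cells cultured with IL-16 expressed more Ifng, Tbx21, Hlx and Furin, 4 of the 24 tested genes of the Th1 list. Ifng, the signature Th1 cytokine, rose 2.19-fold, from 55.5 ± 3.64 FPKM with PBS to 121 ± 2.20 FPKM with IL-16 (SD, n = 2 each; log2 fold change 1.12, SE 0.077, adjusted p = 0.0329). Tbx21, which encodes T-bet, the transcription factor that directs Th1 differentiation, rose 2.07-fold, from 46.5 ± 0.661 to 96.5 ± 7.36 FPKM (log2 fold change 1.04, SE 0.081, adjusted p = 0.0350). Hlx, a homeobox factor that acts with T-bet, went from 9.41 ± 0.0469 to 21.3 ± 1.67 FPKM (log2 fold change 1.10, adjusted p = 0.0358). Furin, a proprotein convertase induced by IL-12 in Th1 cells, rose from 155 ± 1.26 to 392 ± 6.39 FPKM (log2 fold change 1.34, adjusted p = 0.0291). The guanylate-binding protein genes Gbp2 and Gbp10, induced by IFN-γ, rose with them, as did the immunity-related GTPase gene Iigp1.

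Across all tested genes, 26 changed at an adjusted p under 0.05 in limma, of which 19 were higher and 7 lower with IL-16, and 14 of the higher and 4 of the lower genes had a log2 fold change of at least 1 in size on the log2(FPKM + 1) scale. At an unadjusted p under 0.05 there were 1139 higher and 1646 lower genes, and 218 genes lay under an adjusted p of 0.10 (124 higher, 94 lower). In all 26 changed genes both IL-16 values lay on the same side of both PBS values, which was also true of 58.9% of tested genes, against 33.3% by chance. The number of calls depended on which library was left out, in fits where the lone library of a group is assumed to vary like the other group. All 26 genes kept their sign in these fits, which was fixed in advance because their groups do not overlap. Without PBS replicate 1, 9 genes were called and without PBS replicate 2 also 9, with 3 and 2 of the 26 among them. There were 2065 without IL-16 replicate 1 (765 higher, 1300 lower) and 53 without IL-16 replicate 2 (29 higher, 24 lower). No gene was called without the filter on low values (3068 at an unadjusted p under 0.05). In contrast, 53 were called after median-of-ratios scaling, 40 after rescaling to TPM, 43 after a correction for GC content and length and 126 (73 higher, 53 lower) when rows that are copies of a gene were summed.

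Among the genes with the largest rises, Ifi204, an interferon-inducible DNA-sensing protein gene, went from 3.09 ± 0.333 to 12.5 ± 1.90 FPKM (log2 fold change 1.72, adjusted p = 0.0350). The class Ib MHC gene H2-T24 rose from 6.35 ± 0.802 to 19.6 ± 0.138 FPKM (log2 fold change 1.49, adjusted p = 0.0329). Csf1, which encodes the macrophage growth factor M-CSF, rose from 5.78 ± 0.424 to 17.9 ± 0.796 FPKM (log2 fold change 1.48, adjusted p = 0.0329). The serpin gene Serpinb5 (maspin) rose from 5.83 ± 0.562 to 16.8 ± 2.30 FPKM. Scly, which encodes the enzyme that releases selenium from selenocysteine, rose from 27.9 ± 1.01 to 70.8 ± 6.28 FPKM, and Ube2f, which encodes a NEDD8-conjugating enzyme, from 18.0 ± 0.375 to 39.6 ± 2.07 FPKM. H2-T24, Ifi204, Iigp1 and the Gbp genes belong to families of similar genes, between which reads can be split, so their values are uncertain to that extent. In the GENCODE annotation of GRCm38, Ube2f and Scly are neighbouring protein-coding genes on the same strand, as are Furin and Fes and Tbx21 and Tbkbp1. Fes and Tbkbp1, named here after their values were seen, also rose (log2 fold change 1.07 and 0.76, adjusted p = 0.0359 and 0.0405).

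The lower genes included Cebpb, a transcription factor gene of the integrated stress response and of myeloid differentiation, which fell from 48.3 ± 0.379 to 23.4 ± 2.33 FPKM (log2 fold change -1.02, adjusted p = 0.0405). Tiprl, which encodes a regulator of PP2A-type phosphatases, fell from 22.3 ± 0.445 to 11.7 ± 0.109 FPKM (log2 fold change -0.87, adjusted p = 0.0405). Inpp4b, which encodes a phosphatidylinositol 3,4-bisphosphate phosphatase, fell from 42.6 ± 0.153 to 25.4 ± 0.0867 FPKM (log2 fold change -0.72, adjusted p = 0.0413). The row Rps18-2, a copy of the ribosomal protein gene Rps18, fell from 406 ± 17.0 to 92.2 ± 11.4 FPKM (log2 fold change -2.13, adjusted p = 0.0291). The Rps18 row itself was 88.6 and 30.5 FPKM with PBS and 101 and 56.1 FPKM with IL-16. It did not pass in limma (log2 fold change 0.52, adjusted p = 0.577). Summed over the 4 rows of Rps18, the mean was 465 FPKM with PBS and 171 FPKM with IL-16 (log2 fold change -1.46, adjusted p = 0.0308). Reads can be split between such rows and processed pseudogenes. Of the 26 calls, those of Rps18-2 and Evi2 (named after its values were seen) also held without either PBS library and that of H2-T24 without PBS replicate 1. The remaining 23 were lost in both of those fits. Ifng then had an adjusted p of 0.119 and 0.121 (0.0112 to 0.148 over 14 alternatives) and a log2 fold change of 1.18 and 1.05. Tbx21 had an adjusted p of 0.171 and 0.148 (0.00729 to 0.171 over 14 alternatives) and a log2 fold change of 1.02 and 1.05.

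**Figure D2:**
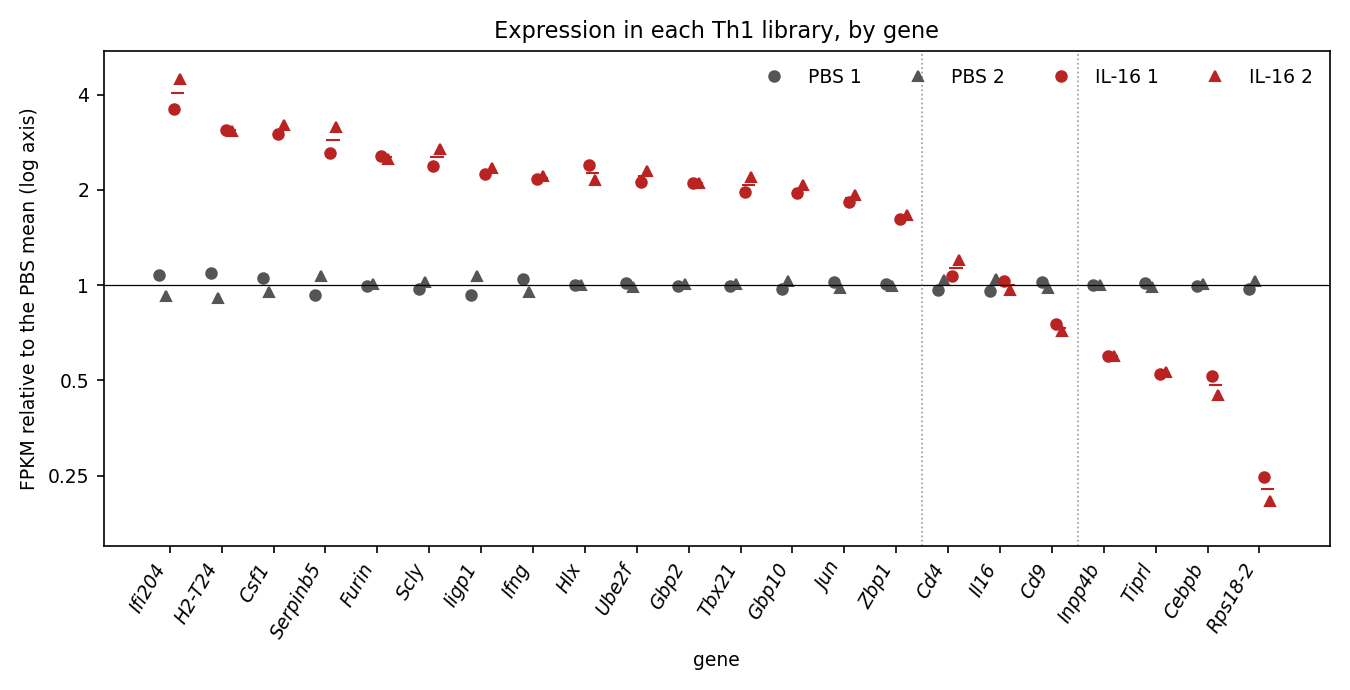
FPKM of each library divided by the PBS mean of the gene, on a log axis, for the named genes that rose (left), for Cd4, Il16 and Cd9, which did not pass the test (middle), and for the named genes that fell (right); circles are replicate 1, triangles replicate 2, and the short red lines are the IL-16 means. Ifng lies 2.19-fold and Tbx21 2.07-fold above PBS on average, while both groups overlap for Il16.

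Il16 and the genes of the described IL-16 receptors did not pass the threshold with all 4 libraries. Il16 was 42.1 ± 2.52 FPKM with PBS and 42.1 ± 2.06 FPKM with IL-16 (SD, n = 2 each), a log2 fold change of -0.0023 with a 95% interval from -0.21 to 0.20 (adjusted p = 0.990). Cd4 differed by 0.18 on the log2 scale, with an interval from -0.059 to 0.41 (adjusted p = 0.307). Cd9 was 12.4 ± 0.373 FPKM with PBS and 9.12 ± 0.296 FPKM with IL-16, with both IL-16 values below both PBS values, but did not pass over all genes (log2 fold change -0.41, interval -0.63 to -0.19, adjusted p = 0.106). It passed when IL-16 replicate 1 was left out (log2 fold change -0.44, adjusted p = 0.0437). The Cd4 difference was 0.095 without IL-16 replicate 2 (adjusted p = 0.462).

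The Th1 list rose as a group at the preset correlation (camera adjusted p = 3.98e-10) but did not pass with an estimated correlation (adjusted p = 0.475). The correlation estimated for this list was -0.00457, below the preset 0.01. The call was therefore not lost through a higher estimated correlation between members. Of the 24 tested members of the Th1 list, 4 rose (Furin, Ifng, Tbx21 and Hlx), none fell and 20 did not pass over all genes. Adjusted over the list alone, 13 rose and none fell. The median log2 fold change of the list was 0.39, with 19 members above 0. The list's median was 0.31 in IL-16 replicate 1 and 0.39 in IL-16 replicate 2 relative to the PBS mean, against 0.016 between the PBS libraries. The list also passed fry, which asks whether its genes move one way (adjusted p = 0.0359).

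The IFN-γ response list, made of genes that cells switch on after IFN-γ binds its receptor, rose at the preset correlation and shared 0 members with the Th1 list. Its camera adjusted p was 3.62e-12, but it did not pass with an estimated correlation (adjusted p = 0.475) or by fry (adjusted p = 0.0502). The correlation estimated for this list was 0.039. Of 34 tested members 3 rose (Gbp2, Gbp10 and Iigp1), none fell and 31 did not pass over all genes. Adjusted over the list alone, 19 rose and none fell. Gbp2 was among the most abundant, rising from 384.5 ± 3.05 to 811 ± 0.230 FPKM (log2 fold change 1.07, adjusted p = 0.0350). Gbp10 rose from 26.7 ± 1.03 to 53.8 ± 2.28 FPKM and Iigp1 from 19.5 ± 1.89 to 44.8 ± 1.32 FPKM. Gbp5 was 71.9 ± 1.85 FPKM with PBS and 114 ± 2.73 FPKM with IL-16 (adjusted p = 0.0514). The median log2 fold change was 0.37, with 0.40 in IL-16 replicate 1 and 0.32 in IL-16 replicate 2.

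Type I interferon-stimulated genes rose by a smaller median of 0.20 over 20 tested members (camera adjusted p = 0.00501, adjusted p = 0.747 with an estimated correlation). Their median was 0.26 in IL-16 replicate 1 and 0.14 in IL-16 replicate 2, and 0.125 over both at a pseudocount of 5. The list did not pass fry (adjusted p = 0.129). In this list 1 member rose over all genes, Zbp1, a sensor of Z-form nucleic acids, from 72.3 ± 0.872 to 118 ± 2.75 FPKM (log2 fold change 0.70, adjusted p = 0.0442). The Zbp1 call was also lost at a pseudocount of 0.1 (adjusted p = 0.051) and with the replicate block (adjusted p = 0.0577). Adjusted over the list alone, 5 rose and 1 fell. The deISGylase gene Usp18 was 13.5 ± 0.672 FPKM with PBS and 26.0 ± 3.40 FPKM with IL-16 (adjusted p = 0.0656), and Stat2 and Irf7 had log2 fold changes of 0.38 and 0.58 (adjusted p = 0.105 for both).

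Lists with smaller upward shifts were the IL-2 and STAT5 targets, the T cell markers and the mitosis genes, and none of their members passed over all genes. The 17 IL-2 and STAT5 targets had a median log2 fold change of 0.069 (camera adjusted p = 0.0167, adjusted p = 0.747 with an estimated correlation), with none higher or lower adjusted over the list alone. Their median was 0.13 without IL-16 replicate 2 and 0.096 without IL-16 replicate 1. In this list Il2rb, the IL-2 receptor beta chain gene, was 424 ± 20.2 FPKM with PBS and 560.2 ± 7.30 FPKM with IL-16 (adjusted p = 0.106), and Gzmb was 661 ± 18.9 and 834 ± 26.2 FPKM (adjusted p = 0.135). The 17 T cell markers had a median of 0.081 (camera adjusted p = 0.0191, adjusted p = 0.747 with an estimated correlation), and adjusted over the list alone 3 rose and 1 fell, among them Cd247 (log2 fold change 0.51, adjusted p over all genes 0.0686). The median of the T cell markers ran from 0.072 to 0.133 over 16 alternatives. The 25 mitosis genes had a median of 0.12 (camera adjusted p = 0.0464, adjusted p = 0.747 with an estimated correlation) and none passed over the list alone. The proliferation marker Mki67 was 60.7 ± 1.23 FPKM with PBS and 83.8 ± 12.2 FPKM with IL-16 (adjusted p = 0.122). Leaving out PBS replicate 1 ended all these calls (adjusted p = 0.0642, 0.0953 and 0.103). Leaving out PBS replicate 2 ended those of the IL-2 list and mitosis (0.0679 and 0.0782), and leaving out IL-16 replicate 2 that of mitosis (0.134), whose median then was 0.029, against 0.14 without IL-16 replicate 1. The IL-2 call was also lost after GC and length correction (0.0550). That of mitosis was also lost without the low-value filter (0.0504), with the stricter filter (0.0618), with copies summed (0.0551) and without ribosomal protein rows (0.0665). Over 16 alternatives the adjusted p ran from 0.000505 to 0.747 for the IL-2 and STAT5 targets, from 0.0069 to 0.747 for the T cell markers and from 0.0276 to 0.747 for mitosis.

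The ribosomal protein and respiratory chain lists were lower at the preset correlation, though no single member passed over all genes. The 41 ribosomal protein genes fell by a median of 0.25 on the log2 scale, with 35 members below 0 and none passing over all genes or over the list alone (camera adjusted p = 0.000562, adjusted p = 0.876 with an estimated correlation). Rps19 was 1248 ± 52.5 FPKM with PBS and 596 ± 224 FPKM with IL-16, and Rps20 was 191 ± 2.11 and 120.1 ± 23.4 FPKM (adjusted p = 0.117 and 0.105). The 47 nuclear-encoded respiratory chain subunits fell by a median of 0.16, with 37 members below 0 (camera adjusted p = 0.0167, adjusted p = 0.876 with an estimated correlation). None passed over all genes and 1 fell adjusted over the list alone, Cox7a2, from 51.4 ± 0.125 to 31.4 ± 4.21 FPKM (adjusted p over all genes 0.0835). The shift was unequal between the IL-16 libraries. The ribosomal median was -0.13 in replicate 1 and -0.40 in replicate 2. The respiratory chain median was -0.081 and -0.30, against 0.042 and 0.021 between the PBS libraries. Ribosomal protein rows made up 16.1% of the summed FPKM in both PBS libraries, 14.8% in IL-16 replicate 1 and 13.0% in IL-16 replicate 2. Without IL-16 replicate 2 the respiratory chain list did not pass (adjusted p = 0.310; 9.56e-06 to 0.876 over 16 alternatives), while the ribosomal list did (adjusted p = 0.000125; 1.26e-09 to 0.876 over 15 alternatives).

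The hypoxia, ATF4 and glutamine lists were also lower at the preset correlation. The estimated correlation between their members was 0.098, 0.37 and 0.27. The ATF4 and glutamine lists share 4 tested members, so they are not independent results. The median log2 fold change of all tested genes was -0.0445. After median-of-ratios scaling the medians of the 3 lists were -0.057, -0.109 and -0.145. The 20 hypoxia response genes fell by a median of 0.10 on the log2 scale (camera adjusted p = 0.0191, adjusted p = 0.747 with an estimated correlation). None of them passed over all genes and 6 fell adjusted over the list alone, among them Ankrd37 (38.5 ± 1.26 to 21.8 ± 2.46 FPKM, adjusted p over all genes 0.0656) and the mitophagy receptor gene Bnip3 (213 ± 3.15 to 168 ± 5.31 FPKM, adjusted p over all genes 0.106). The 32 ATF4 and amino acid response genes fell by a median of 0.16 (camera adjusted p = 0.0201, adjusted p = 0.876 with an estimated correlation), with 1 member, Cebpb, lower over all genes and over the list alone. The 28 genes of glutamine and glutamate metabolism fell by a median of 0.19 (camera adjusted p = 0.0464, adjusted p = 0.876 with an estimated correlation). None passed over all genes and 1 fell adjusted over the list alone. Glud1 and the glutamine transporter gene Slc1a5 had log2 fold changes of -0.31 and -0.27 (adjusted p = 0.135 and 0.159). The glutamine median was -0.077 in IL-16 replicate 1 and -0.24 in IL-16 replicate 2, the ATF4 median -0.086 and -0.18, and the hypoxia median -0.11 and -0.17. The hypoxia call was lost without PBS replicate 1 or 2 (adjusted p = 0.0953 and 0.0679; 0.00338 to 0.747 over 16 alternatives), and the ATF4 call without PBS replicate 2 (0.0782; 0.00638 to 0.876). The glutamine call was lost without PBS replicate 1, PBS replicate 2 or IL-16 replicate 2 (0.0953, 0.0838 and 0.149; 0.0342 to 0.876), and under 5 other alternatives apart from fry and the estimated correlation (0.0515 to 0.0716).

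**Figure D3:**
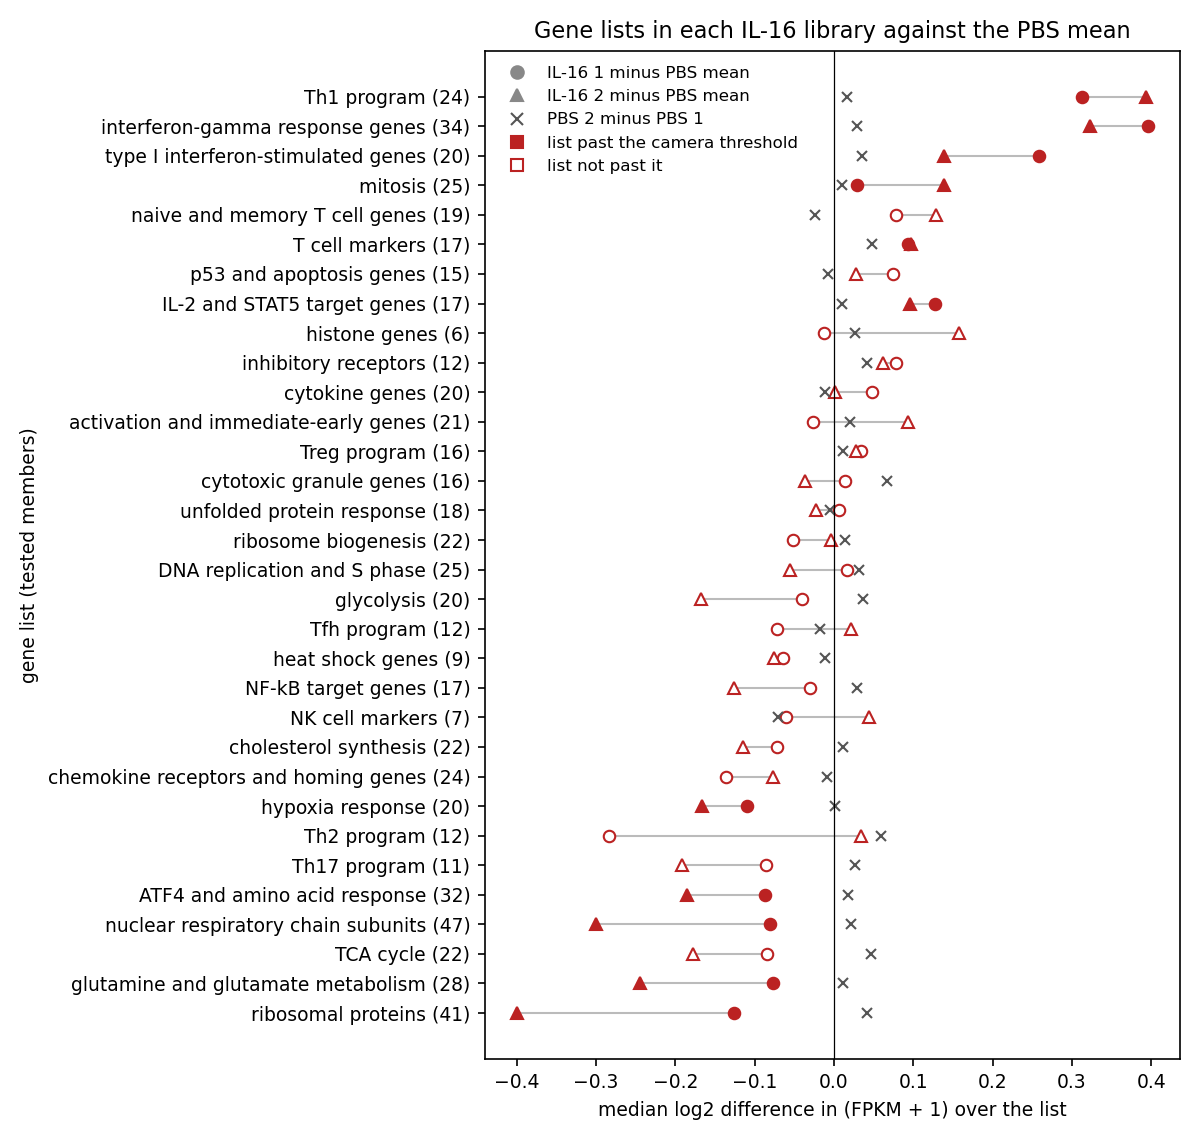
Median log2 difference in (FPKM + 1) over each tested gene list, for IL-16 replicate 1 (circles) and IL-16 replicate 2 (triangles) against the PBS mean, with crosses for the difference between the PBS libraries and the number of tested members in brackets; filled symbols mark the 11 lists past the camera threshold at the preset correlation, of which 0 passed with an estimated one. The Th1 list lies at 0.31 and 0.39 and the ribosomal proteins at -0.13 and -0.40.

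Programs of the other T helper subsets did not shift past the camera threshold. Counts adjusted over a list alone, here and below, stand beside 2785 of 11882 tested rows at an unadjusted p under 0.05. The 11 Th17 genes had a median log2 fold change of -0.14 (camera adjusted p = 0.300, fry adjusted p = 0.0409). None passed over all genes, and adjusted over the list alone 1 was higher and 4 lower. Among them Il22 was 15.6 ± 0.641 FPKM with PBS and 8.81 ± 0.559 FPKM with IL-16 and Il17a 2.29 ± 0.290 and 0.813 ± 0.124 FPKM (adjusted p over all genes 0.0630 and 0.0973). The 12 Th2 genes had a median of -0.10 (camera adjusted p = 0.731; 1 lower adjusted over the list alone), with Ccr8 at 8.51 ± 0.275 and 5.37 ± 0.0130 FPKM and Il4 at 3.41 ± 0.484 and 2.10 ± 0.710 FPKM (adjusted p over all genes 0.0875 and 0.202). The 16 Treg genes had a median of 0.013 (camera adjusted p = 0.195; 4 higher and 1 lower adjusted over the list alone), with the ectonucleotidase gene Entpd1 at 16.9 ± 0.895 and 25.6 ± 1.32 FPKM and Foxp3 at 11.2 ± 0.640 and 17.2 ± 3.89 FPKM (adjusted p over all genes 0.0797 and 0.143). The 12 Tfh genes had a median of -0.061 while camera pointed upward (adjusted p = 0.574; 1 higher and 1 lower adjusted over the list alone), with Sh2d1a, the SAP adaptor gene, at 43.1 ± 0.613 and 21.0 ± 2.80 FPKM (adjusted p over all genes 0.0514).

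The cytokine, cytotoxic granule, inhibitory receptor and homing lists did not pass camera. Of 20 tested cytokine genes 2 rose over all genes, Csf1 and Ifng, and 4 were higher and 4 lower adjusted over the list alone. The list passed fry (adjusted p = 0.0409) but not camera (adjusted p = 0.361), and it holds 3 Th1 list members. The 16 cytotoxic granule genes had a median of 0.0057 while camera pointed downward (adjusted p = 0.950), with none passing over all genes and 3 higher and 4 lower adjusted over the list alone. Nkg7, a granule protein gene of cytotoxic and Th1 cells, was 66.1 ± 2.73 FPKM with PBS and 103 ± 2.30 FPKM with IL-16. In contrast, Gzma was 230.1 ± 8.59 and 163 ± 17.4 FPKM and Gzme 13.2 ± 0.283 and 7.76 ± 0.321 FPKM (adjusted p over all genes 0.0587, 0.105 and 0.0656). The 12 inhibitory receptor genes had a median of 0.055 (camera adjusted p = 0.176; 5 higher and 1 lower adjusted over the list alone), with Lag3 at 128 ± 3.54 and 168 ± 8.62 FPKM and Cd200r1 at 4.47 ± 0.214 and 2.48 ± 0.0426 FPKM (adjusted p over all genes 0.105 and 0.0973). Of 24 chemokine receptor and homing genes (median -0.090, camera adjusted p = 0.574), none passed over all genes and 3 were higher and 6 lower adjusted over the list alone. In this list Ccr2 was 19.0 ± 0.419 FPKM with PBS and 11.9 ± 1.32 FPKM with IL-16 (adjusted p over all genes 0.0873).

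The activation, naive and memory and NF-kB lists did not pass camera either. Of 21 activation and immediate-early genes (median 0.018, camera adjusted p = 0.574) 1 rose over all genes, the AP-1 subunit gene Jun, from 52.9 ± 1.84 to 99.3 ± 3.44 FPKM (log2 fold change 0.90, adjusted p = 0.0350). Adjusted over the list alone, 3 were higher and 4 lower, and Egr3 was 11.6 ± 0.297 and 7.59 ± 0.0165 FPKM (adjusted p over all genes 0.0849). The 19 naive and memory T cell genes had a median of 0.095 and a mean of -0.0039 (camera, upward, adjusted p = 0.361), with 1 higher and 1 lower adjusted over the list alone. The lower one was Klf2, a quiescence factor gene, with 16.8 ± 0.808 FPKM with PBS and 9.86 ± 0.574 FPKM with IL-16 (adjusted p over all genes 0.0656). The 17 NF-kB targets had a median of -0.070 (camera adjusted p = 0.977; 3 higher and 2 lower adjusted over the list alone), with Icam1 at 32.4 ± 0.923 and 44.9 ± 0.103 FPKM (adjusted p over all genes 0.0831).

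Metabolic, stress and growth lists that did not pass camera were the following, none with a member past the threshold over all genes. The 22 TCA cycle genes had a median of -0.17 (adjusted p = 0.204), with 3 lower adjusted over the list alone, among them the fumarase gene Fh1 (18.5 ± 0.168 and 12.1 ± 0.455 FPKM, adjusted p over all genes 0.0686). Glycolysis (20 genes, median -0.058, adjusted p = 0.574) and cholesterol synthesis (22 genes, median -0.085, adjusted p = 0.415) had no member past the threshold over the list alone. Heat shock genes (9 genes, median -0.070, adjusted p = 0.783) had 1 higher and 2 lower over the list alone. No member passed over the list alone for p53 and apoptosis (15 genes, median 0.078, adjusted p = 0.361), the unfolded protein response (18 genes, median -0.014 with camera upward, adjusted p = 0.731), S phase (25 genes, median -0.025 with camera upward, adjusted p = 0.928) or ribosome biogenesis (22 genes, median -0.020, adjusted p = 0.928). The same held for 6 histone genes (median 0.058, mean -0.021, adjusted p = 0.783) and 7 NK cell markers (median -0.071 with camera upward, adjusted p = 0.977).

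In total 11 of the 32 tested lists passed camera with a preset correlation of 0.01, 6 upward and 5 downward. With a correlation estimated from these libraries 0 passed, the smallest adjusted p being 0.475, and 2 lists had an unadjusted p under 0.05. The fry test called 3 lists, the Th1 and cytokine lists upward and the Th17 list downward. On simulated data of this design, the estimated correlation called 0 of 10 lists shifted by 0.4 on the log2 scale, and the preset one called 10 of 10. The simulated genes varied independently. The simulation therefore cannot tell how far the preset correlation miscalls lists whose members move together, such as the ribosomal proteins (estimated correlation 0.74).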

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

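The scaling, stricter filter, copy-summing, GC and length, and ribosomal-row alternatives were chosen after the data were seen. The planned count-based alternatives were not run because the values are not counts. Every alternative reused the same libraries, in which the groups of the 26 called genes do not overlap. A kept sign is therefore no independent support. All 26 called genes kept their sign in each of 359 gene-by-alternative values, and 271 of these stayed past the threshold. The number of called genes was 0 with limma without the low-value filter (19465 genes tested, 3068 at an unadjusted p under 0.05), 53 after median-of-ratios scaling (40 higher, 13 lower), 40 after rescaling to TPM (29 and 11), 43 after GC and length correction (31 and 12) and 126 with copies summed (73 and 53; 23 of the 26 among them), and the causes were not tested. Leaving out 1 library gave 9 to 2065 genes: 9 without PBS replicate 1, 9 without PBS replicate 2, 53 without IL-16 replicate 2 (29 and 24) and 2065 without IL-16 replicate 1 (765 and 1300); the lone library of a group is assumed there to vary like the other group. The other alternatives gave 18 to 39 genes: 24 and 39 at pseudocounts of 0.1 and 5, 18 at a minimum of 1 on the log2(FPKM + 1) scale, 35 with the stricter filter and 35 without ribosomal protein rows. With the replicate block 31 genes were called (18 of the 26 among them) and the glutamine list did not pass (adjusted p = 0.0515). The calls lost with the block included Gbp2, Tiprl and Tbkbp1 (limma adjusted p = 0.0525 each), Inpp4b (0.0546) and Zbp1 (0.0577). The correlation of deviations between libraries of the same number was 0.0067, which gives no sign of pairing, but whether the numbers pair the samples is not stated. The log2 fold changes of Evi2 and Dffa-2, named after their values were seen and near 0 FPKM with IL-16, depended on the pseudocount, from -5.94 to -1.32 and from -4.07 to -0.49.

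Of the gene lists, 0 were called with an estimated correlation and 3 with fry, 6 to 11 with 1 library left out (6 without either PBS library) and 9 to 11 under the rest. The Th1 median of 0.39 lost its call with the estimated correlation, and the IFN-γ median of 0.37 with the estimated correlation (adjusted p = 0.475) and with fry (0.0502). Over their alternatives these medians ranged from 0.31 to 0.43 and from 0.32 to 0.41, with adjusted p from 1.24e-11 to 0.475 and from 1.39e-16 to 0.475. The glutamine list kept its call in 6 of 16 alternatives and mitosis in 7 of 16. The Il16 change, near 0, turned positive after median-of-ratios scaling (0.045) and rescaling to TPM (0.026), and ran from -0.062 to 0.057 with 1 library left out (0.047 without IL-16 replicate 2). Read depth limits low genes, but it is unknown here.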

Other observations

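The matched-list, marker, single-library, copy-sum, split and neighbour tests in this part were chosen after the results were seen, as were the genes named, whose adjusted p-values come from the limma test of all genes unless copies are summed. For the neighbour tests, the limit of 0.10, the exclusion of names that share their first letters and the use of strand were set after the pairs had been seen.

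Several genes outside the fixed lists passed the limma threshold. Fes, which encodes a non-receptor tyrosine kinase, was 6.13 FPKM with PBS and 14.0 FPKM with IL-16 (log2 fold change 1.07, adjusted p = 0.0359). Tbkbp1, an adaptor of the kinase TBK1, was 44.6 and 76.5 FPKM (log2 fold change 0.76, adjusted p = 0.0405), and Serpina3f 4.56 and 10.8 FPKM (log2 fold change 1.09, adjusted p = 0.0413). An unnamed assembled transcript, Mus_musculus_newGene_95, fell from 20.8 to 10.5 FPKM (log2 fold change -0.93, adjusted p = 0.0359). Evi2 was 9.15 and 6.16 FPKM in the PBS libraries, 0.0528 FPKM in IL-16 replicate 1 and listed at 0 in IL-16 replicate 2 (adjusted p = 0.0329), while the genes it overlaps, Evi2a and Evi2b, went from 4.49 to 4.27 FPKM and from 12.7 to 25.8 FPKM (adjusted p = 0.811 and 0.137).

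Of the genes with an adjusted p between 0.05 and 0.10, for which no change is claimed, a few were picked by eye and no theme among them was tested. Ly6c2 was 38.8 FPKM with PBS and 104 FPKM with IL-16, Ly6c1 389.7 and 661 FPKM and Ly6i 5.43 and 11.6 FPKM (adjusted p = 0.0733, 0.0927 and 0.0514). Ffar2, a receptor for short-chain fatty acids, was 20.9 and 43.4 FPKM (adjusted p = 0.0519), Slamf7 39.5 and 63.1 FPKM (0.0656), P2rx7 36.0 and 57.1 FPKM (0.0627) and Irf1 121 and 182 FPKM (0.0666). Lower with IL-16 were Ifngr2, an IFN-γ receptor subunit, with 14.2 and 8.31 FPKM (0.0615), the transferrin receptor gene Tfrc with 42.5 and 25.3 FPKM (0.0630), Jak2 with 81.2 and 57.3 FPKM (0.0699) and Rpl22l1 with 106 and 29.9 FPKM (0.0732).

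The rise of the Th1 and IFN-γ response lists was set against technical explanations. Log2 fold changes rose with GC content, from a median of -0.13 in the lowest decile of genes to 0.017 in the highest. Yet the list medians of 0.39 and 0.37 lay above the upper limits of 0.072 and 0.070 for 10000 random lists matched on GC content, length and level. A larger share of NK or CD8 T cells would raise their markers about as much as Ifng (log2 ratio 1.13). However, 9 such markers had a median log2 ratio of 0.069 and a mean of -0.0615 (SE of the mean over markers 0.089). That SE does not measure the spread between libraries. Of the 3 splits of the 4 libraries, 1, the real one with 26 genes, gave that many, and the highest other gave 1. The other splits put a PBS and an IL-16 library in each group. Any difference between PBS and IL-16 then adds to the spread, so few calls could result. The 3 splits are also too few to set against chance. A response to IL-16, the difference the design names, and an unrecorded difference between the cultures both remain open.

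The fall of the ribosomal protein and respiratory chain lists was larger in IL-16 replicate 2, and a response to IL-16 and a difference in RNA quality or culture state between libraries were not tested and stay open. Their medians of -0.25 and -0.16 lay below the lower limits of -0.13 and -0.12 for random lists matched on GC content, length and level. Medians of random lists spread less than those of lists whose members move together, as here. The limits are therefore too narrow to exclude GC content, length or level as the cause. The ribosomal median was -0.126 in replicate 1 and -0.40 in replicate 2, beside 0.042 between the PBS libraries. The estimated correlation between members was 0.74 and 0.64, so each list is close to a single measurement per library. Without replicate 2 the ribosomal list passed camera at the preset correlation of 0.01 (adjusted p = 0.000125), which lies far below the estimated one, so whether the fall rests on replicate 2 cannot be told from these libraries.

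Reads shared between rows of the table are a candidate explanation for some of the calls. With copies summed, Rps6kb2 had a log2 fold change of 0.31 (SE 0.082, adjusted p = 0.0982). It would be 0.62 if the row Rps6kb2-2 alone had changed, so the sum is as exchange of part of the reads predicts. The sum over the Rps18 rows remained lower at -1.46 (adjusted p = 0.0308), against -1.61 if Rps18-2 alone had changed. The Rps18 row itself had a log2 fold change of 0.52 and did not pass. For Dffa the sum of -0.195 decides nothing, since the change of Dffa-2 alone would give -0.218. Among 183 genes under an adjusted p of 0.10 that could be placed on the chromosomes, 13 pairs of neighbours among tested genes, pairs of names with the same first letters left out, had fold changes in the same direction (10 without 3 pairs of related GTPase genes), against an upper limit of 4 in shuffled orders (one-sided permutation p = 1e-04, the smallest that 10000 shuffles can give). Of these pairs 84.6% lay on the same strand, against 46.8% of all neighbour pairs (exact binomial p = 0.00942), but without the GTPase pairs it was 8 of 10 (exact binomial p = 0.0533), some of the pairs share a gene, and strand was looked at because of pairs already seen, so strand does not settle whether reads run from one gene into the next. Shared reads, shared regulation of neighbours and, for the GTPase pairs, shared sequence stay open. Reads from Fes (6.13 and 14.0 FPKM) are too few to make the rise of Furin (155 to 392 FPKM). In the direction of transcription, however, Furin comes before Fes and Tbkbp1 before Tbx21. Reads running on would go from Furin into Fes, and from Tbkbp1 (44.6 to 76.5 FPKM) into Tbx21 (46.5 to 96.5 FPKM). Neither was tested.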
